A study of Arabidopsis thaliana with 4 samples.

How the data were processed

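RNA was sequenced from nuclear fractions of Arabidopsis leaves, as an input and a GFP-Trap immunoprecipitate (IP) of an MTA-GFP line and of a control line, with 1 library in each of the 4 groups. Per the labels' protocols, the tissue was crosslinked with formaldehyde, RNA was recovered with phenol and chloroform, and libraries were made with a directional kit. Groups were taken from the sample titles. The genotype field calls the control CFP where the titles say GFP.

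Per the submitters' processing notes, the tools were Trimmomatic, Bowtie, HISAT2 and Salmon and the build was TAIR10. Their roles, order and versions, and the strand setting of the counting, are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited tables hold, per the file headers, an estimated count of reads and a TPM value for each of 55524 entries. The entries comprise transcripts, microRNA precursors and primary transcript models, organelle transcripts, 1429 structural RNA entries without a locus and 2 spike-in controls. Salmon divides reads that match several entries, so values of near-identical copies are uncertain. Of the loci compared, 98.2% had a mean deposited TPM below 0.5.

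Estimated counts were summed per locus and rounded to whole numbers. All 32548 nuclear or MIR loci matched the reference gene table (assembly TAIR10.1), which was used only for symbols, gene types and neighbours. No genome sequence was used here. The 133 chloroplast and 152 mitochondrial entries and the entries without a locus were left out of the ratios of loci and kept in the shares of reads. Loci within 10 kb of a ribosomal RNA gene (13 loci, those genes included) were counted as ribosomal DNA in the shares, except MIR5642a, which was counted with the MIR loci. The 2 spike-in entries had 0 reads in every library, where 3 reads would be a share of 6.64e-06% to 8.31e-06%.

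Of 24235 loci with reads, 15669 with at least 40 reads over the 4 libraries were compared. Library factors were TMM factors from edgeR 4.0.16 in R 4.3.3 over these loci, at 0.641 for the MTA-GFP input, 2.37 for the MTA-GFP IP, 1.13 for the control input and 0.581 for the control IP. With 0.5 reads added, 4 log2 ratios were formed: MTA-GFP IP over input, control IP over input, the double ratio (the first divided by the other), and MTA-GFP input over control input. Ratios of 2 libraries have exact conditional (Clopper-Pearson) 95% intervals, and double ratios have intervals from the Poisson variances on the log scale. A locus counts as higher or lower when its ratio is at least 2-fold and its interval leaves out 1. No p-value is given for the ratios of single loci, since each group holds 1 library. Shares of reads have Wilson intervals and reads per library depth (RPM) exact Poisson intervals. Where a library had 0 reads, a bound was computed against 3 reads in that library and is written as at least N-fold; it takes the other libraries' reads as exact. Total reads were 43950307, 36098699, 40011502 and 45198238 in the order above, of which 1011670, 3044241, 1722892 and 955605 fell on nuclear mRNA, so loci of low expression have wide intervals.

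The 22 gene lists (235 listed loci besides the lists taken from gene types) were fixed before the data were examined: m6A writers, readers and erasers, miRNA biogenesis, miRNA targets, photosynthesis, the clock, salicylate, wound and touch, heat shock and SR genes, markers of guard cells, phloem, trichomes and flowers, cytosolic ribosomal proteins, and snoRNA, snRNA, other non-coding, pseudogene and MIR loci, the last also as conserved families and as loci with a transcript model. Lists of genes without an intron and of transposable element genes were planned and not run. A list's median is given with its percentile among 10000 random lists of the same size drawn in 20 bins of mean expression, as a description of these libraries. Medians are given for lists with at least 3 measured members.

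The loci named are, in each ratio, the 10 highest and 10 lowest past the size rule, ranked by the end of the interval nearest 0, in the double ratio also the 6 highest and 6 lowest MIR loci, the MTA locus, and up to 4 members per list, those with the most reads and with the largest ratios. This rule was fixed before the data were examined. Other members named in the text, among them HESO1, ECT11, ZAT12, ZAT10, VSP2, DDL, CBF2 and CBF3, and the loci AT1G15405 and AT2G16586 outside the ratios whose rule names them, were chosen after their values were seen.

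The procedure was tested on simulated counts drawn from the real means and library sizes. The draws held counting error only, with no variation between preparations. Rates of calls at unchanged loci therefore do not tell how many real calls come from such variation. In the double ratio it found 24 of 50 loci raised 2-fold, 44 of 50 raised 4-fold, 18 of 50 lowered 2-fold and 42 of 50 lowered 4-fold, and called 408 of 15459 unchanged loci. In MTA-GFP IP over input it found 25, 50, 20 and 45 of 50 and called 164. TMM factors were recovered within 0.245%, and 7 of 100 unchanged lists fell outside the central 95% of random lists.

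Alternatives were DESeq2 1.42.0 size factors, total reads of nuclear genes or of all genes, the deposited TPM values with a pseudocount of 0.5, a prior count of 5, minimums of 10, 200 and 1 reads, a 3-fold rule, no interval, single transcripts, and the 2 IPs compared without inputs. Total mRNA reads, shares per 18S read and outside organelles, per mRNA read, and values without MTA, AT2G16586, AT1G15405, the 2 unnamed entries of 18S length, MIR775, MIR4228 with MIR5642a, or the mitochondrial DNA copy and ribosomal DNA were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.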

Results

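Nuclear RNA of Arabidopsis thaliana Col-0 leaves was profiled before and after immunoprecipitation of MTA, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA. The tissue was crosslinked with formaldehyde, nuclei were isolated, and GFP-tagged MTA was captured on GFP-Trap beads, which carry a GFP-binding protein. RNA was sequenced from 4 libraries: an input and an immunoprecipitate (IP) of MTA-GFP plants, and an input and an IP of a control line. The control is called GFP in the sample titles and CFP in the genotype field, and is named only "control" here. The tissue is given both as leaf and as aerial tissue. The files assigned 43950307 reads to the MTA-GFP input, 36098699 to the MTA-GFP IP, 40011502 to the control input and 45198238 to the control IP. Each group holds 1 library, so no difference has a replicate check. The intervals given are 95% intervals for counting error only, and they treat reads as independent. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. A comparison of 2 libraries compares those libraries and not the conditions behind them.

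The MTA transcript (AT4G10760) separated the libraries as their labels say. Normalised to the depth of each library as RPM, it took 52.1 in the MTA-GFP input (95% interval 50.01 to 54.3) and 356 in the MTA-GFP IP (350 to 362). In the control it took 1.60 (1.23 to 2.04) in the input and 0.686 (0.466 to 0.974) in the IP. After scaling to the typical nuclear locus, MTA was 62.8-fold higher in the MTA-GFP input than in the control input, a log2 ratio of 5.97 (5.63 to 6.37). The log2 ratio of MTA-GFP IP over input at this locus was 0.60 (0.54 to 0.67), and that of control IP over input was -0.08 (-0.75 to 0.56).

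The first comparison concerns the classes of RNA recovered with MTA-GFP and with the control. Nuclear mRNA made up a larger part of the MTA-GFP IP than of its input, and a smaller part of the control IP than of its input. It took 2.30% of reads in the MTA-GFP input (95% Wilson interval 2.30 to 2.31) and 8.43% in the IP (8.42 to 8.44), against 4.31% in the control input (4.30 to 4.31) and 2.11% in the control IP (2.11 to 2.12). The share was 3.66-fold as large in the MTA-GFP IP as in its input and 0.491-fold as large in the control IP, a double ratio of 7.46 (7.44 to 7.49). Chloroplast RNA went the other way, from 19.6% of the MTA-GFP input to 5.88% of the IP, and from 22.1% of the control input to 49.8% of the control IP.

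Mitochondrial RNA was lower in both IPs, at 0.229% against 1.54% in the MTA-GFP pair and at 1.03% against 2.17% in the control pair. Loci of the ribosomal DNA took 41.7% of the MTA-GFP input and 38.8% of its IP, and 44.0% and 24.2% in the control. Unnamed structural RNA entries took 34.1% and 45.1% in the MTA-GFP pair, and 26.3% and 22.4% in the control pair. Most of these reads lay in 2 entries of the length of the 18S genes, and the other entries of the class rose in both pairs, from 3.60% to 15.5% with MTA-GFP and from 2.72% to 5.33% with the control. Counted with the ribosomal DNA, the 2 entries bring it to 72.1% and 68.4% in the MTA-GFP pair and to 67.6% and 41.3% in the control pair. The named snoRNA and snRNA genes together took 0.723% and 0.701% in the MTA-GFP pair, and 0.995% and 0.260% in the control pair. Nuclear non-coding RNA genes outside the snoRNA, snRNA and MIR loci went from 0.0399% to 0.866% with MTA-GFP and from 0.0597% to 0.188% with the control, 21.7-fold and 3.14-fold. The locus AT1G15405 alone held 271014 reads of the MTA-GFP IP and 67598 of the control IP, and without it the class was 4.38-fold in MTA-GFP IP over input and 0.660-fold, thus lower, in control IP over input. Among reads outside organelles the mRNA double ratio was 4.07, and per 18S rRNA read it was 5.55. Without AT2G16586, which held 132035 reads of the control IP, the mRNA double ratio was 8.57.

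**Figure D1:**
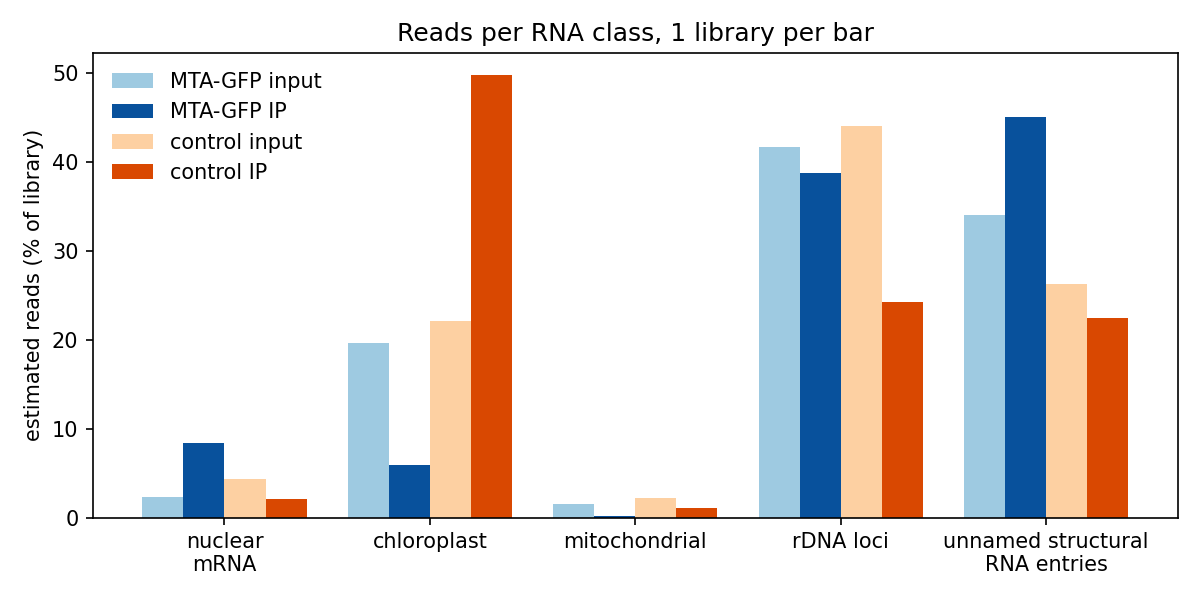
Percent of all assigned reads per RNA class (y axis) in each of the 4 libraries, 1 bar per library. Nuclear mRNA takes 8.43% of the MTA-GFP IP and 2.11% of the control IP, and chloroplast RNA takes 5.88% and 49.8%.

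Because these classes differ so much between libraries, the ratios of single loci depend on the scale. TMM scaling sets the typical nuclear-encoded locus near a log2 ratio of 0, and all ratios below are relative to it unless a share of reads is named. Scaled to all reads, the median of 15669 tested loci moves by 3.26 in the double ratio, 2.14 in MTA-GFP IP over input, -1.11 in control IP over input and -0.94 in MTA-GFP input over control input. Scaled to all nuclear-encoded reads the moves are 2.28, 2.02, -0.25 and -0.80, and scaled to mRNA reads they are 0.41, 0.29, -0.11 and -0.05.

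The series title names methylation of primary microRNA transcripts by MTA, so the MIR loci come next. As a share of reads, transcripts of the loci with a primary transcript model were more abundant in the MTA-GFP IP than in its input, and less abundant in the control IP than in its input. Relative to the typical nuclear locus they were higher in both IPs by similar amounts. The 54 loci with a model of the primary transcript held 143 reads (3.25 RPM, 2.74 to 3.83) in the MTA-GFP input and 737 (20.4 RPM, 18.97 to 21.9) in the MTA-GFP IP, against 213 (5.32 RPM, 4.63 to 6.09) in the control input and 3.52 RPM (2.99 to 4.11) in the control IP. On the share of reads the pooled loci were 6.25-fold in MTA-GFP IP over input and 0.662-fold in control IP over input, a double ratio of 9.45 (7.20 to 12.4). On TMM-scaled reads the same values were 1.39-fold (1.16 to 1.68) and 1.46-fold (1.18 to 1.80), and the double ratio of 0.957 (0.729 to 1.26) included 1. Per mRNA read they were 1.71-fold (1.43 to 2.06) in MTA-GFP IP over input and 1.34-fold (1.09 to 1.66) in control IP over input, and a difference between these enrichments was not detectable at this depth (double ratio 1.27, 0.969 to 1.67). The MTA-GFP IP over the control IP was 1.45-fold (1.22 to 1.74) per mRNA read and 1.14-fold (0.957 to 1.36) on TMM-scaled reads. All MIR loci summed, precursors without a transcript model included, were 14.6-fold on the share of reads in MTA-GFP IP over input and 5.16-fold in control IP over input, a double ratio of 2.82 (2.51 to 3.16). MIR4228 and MIR5642a held 1787 and 2322 of the 4360 control IP reads of this class, and without them the values were 5.37, 0.699 and 7.68.

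Of 325 MIR loci, 103 had a read and 17 passed the minimum of 40 reads over the 4 libraries. Their median log2 double ratio was -0.03 relative to the typical locus and 3.20 on the share of reads, with 1 locus higher, 5 lower and 11 neither by the size rule (at least 2-fold with an interval off 1). Over the 103 loci with a read the median was 0.81, and without MIR4228 and MIR5642a it was 0.18. The median of the 17 loci in MTA-GFP IP over input was 0.89 relative to the typical locus (5 higher, 3 lower) and 2.96 on the share of reads. The median of control IP over input was 0.93 relative to the typical locus (4 higher, 1 lower) and -0.17 on the share of reads. Over the 103 loci with a read it was 0, or -0.013 after subtracting the shift of all loci. A value of exactly 0 is that of a locus without reads in either control library. Among 10000 random lists matched on expression, the 3 medians of the 17 loci relative to the typical locus lay at percentiles 25.4, 99.7 and 99.9. The 8 measured loci of conserved families had medians of 0.51, 0.64 and 0.55 in the same 3 ratios. The 12 measured loci with a transcript model had 0.58, 1.02 and 0.92. The minimum of 40 sums unscaled reads, to which the MTA-GFP IP contributes most. Loci such as MIR472, with 3, 38, 9 and 3 reads, passed it through that library. This can raise the medians and higher calls in MTA-GFP IP over input and in the double ratio. The pooled 54 loci, which had no minimum, were 1.39-fold in MTA-GFP IP over input on TMM-scaled reads.

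MIR779 was the 1 MIR locus past the size rule upward in the double ratio, at 2.51 (0.17 to 4.85) from 5, 35, 13 and 2 reads in the MTA-GFP input, MTA-GFP IP, control input and control IP, but the deposited TPM values turn it to -0.24. MIR472 at 2.27 (-0.10 to 4.64), MIR170 at 1.74 (-0.16 to 3.64), MIR159a at 0.96 (-0.94 to 2.87), MIR157c at 0.89 (-0.84 to 2.61) and MIR166a at 0.83 (-1.33 to 3.0) had intervals that included 0. MIR159a, whose product targets GAMYB-like transcription factors, was higher in both IPs, at 2.36 (0.82 to 4.75) with MTA-GFP and 1.36 (0.19 to 2.68) with the control. The lowest was MIR5642a at -4.92 (-5.48 to -4.35), which lies beside ribosomal DNA and held 2322 reads of the control IP. MIR775 at -2.86 (-4.09 to -1.63), MIR841b at -2.46 (-4.51 to -0.40), MIR4228 at -1.49 (-1.74 to -1.24) and MIR167d at -1.24 (-2.41 to -0.06) were lower, and MIR159b was at -1.12 (-2.54 to 0.30). The TPM values turn MIR4228 to 0.14 and MIR167d to 0.036. On the share of reads the double ratios of MIR775, MIR841b, MIR4228, MIR167d and MIR159b are above 0, because the shift of 3.26 exceeds their size. MIR4228, known only by its precursor, was higher in both IPs, at 2.32 (2.16 to 2.49) with MTA-GFP and 3.81 (3.62 to 4.01) with the control.

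**Figure D2:**
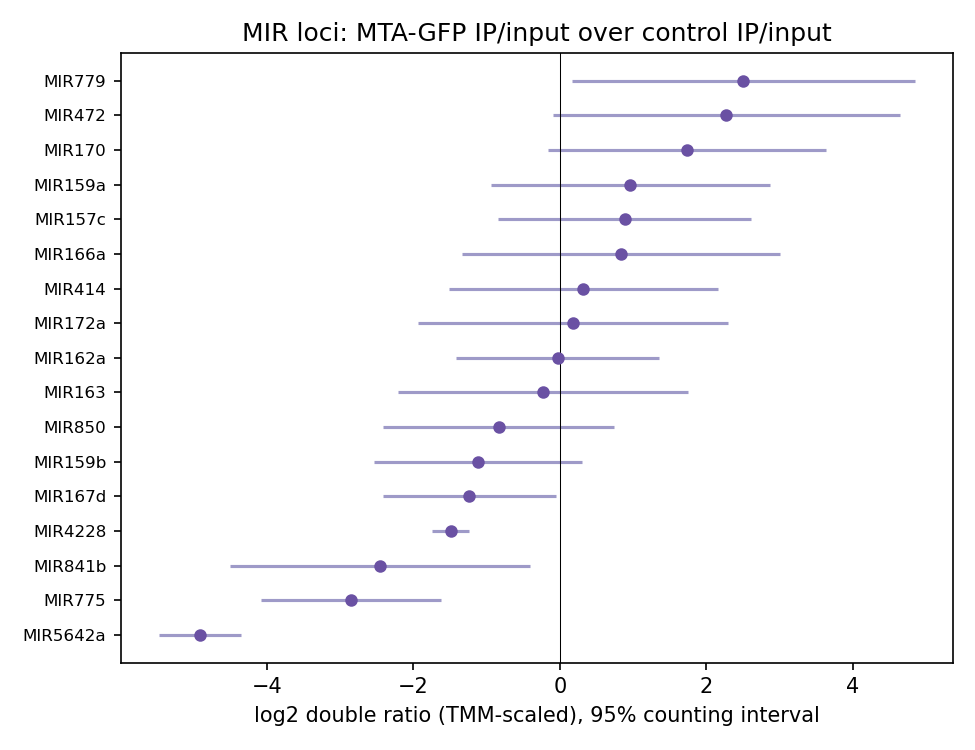
Log2 double ratio relative to the typical nuclear locus (x axis) of the 17 MIR loci with at least 40 reads, with 95% counting intervals as lines. MIR779 at 2.51 is the 1 locus past the size rule upward, and 5 loci lie past it downward, MIR5642a lowest at -4.92; on the share of all reads each value is about 3.26 higher, which leaves MIR5642a as the 1 locus below 0.

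The double ratio sets the enrichment with MTA-GFP against the enrichment with the control at each nuclear locus. Genes of photosynthesis, phloem markers and snoRNA genes were lower in it relative to the typical locus, while the loci highest in it were mostly ones with few or no control IP reads. Of 15669 loci, 1376 were at least 2-fold higher with an interval off 1 and 1399 were lower. Of these, 66 and 11 had a library with 0 reads, and with the 0 set to 3 reads 48 and 11 remained past 2-fold. The split depends on the scale. Of all calls, 49.6% were higher here, against 99.8% when scaled to all reads, 99.5% to nuclear-encoded reads, 81.1% to mRNA reads and 38.3% on the deposited TPM values, where 36 loci were higher and 58 lower. In data simulated for this ratio, 24 of 50 loci raised 2-fold and 44 of 50 raised 4-fold were found, and 2.64% of unchanged loci were called. The simulated data, here and in the self-tests below, held counting error only and no variation between preparations.

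AT1G56660 was 10.6-fold higher in the double ratio, a log2 of 3.40 (2.99 to 3.81). It had 411, 513, 3678 and 60 reads in the MTA-GFP input, MTA-GFP IP, control input and control IP. Scaled, these were 642, 217, 3242 and 103 reads, so it was lower in both IPs than in their inputs. The other 9 highest loci each had a library with 0 reads. UGT75B1, a glucosyltransferase, had 0 of its reads in the control IP against 243 in the control input and was at least 15.4-fold higher. AT4G27480 was at least 18.5-fold higher, AT1G06000 at least 14.9-fold, the long non-coding AT2G08470 at least 10.6-fold and GER2, a germin-like protein, at least 8.21-fold. AT1G24881 was at least 12.4-fold higher, but it has near-identical copies between which reads may be misassigned, and its value is uncertain. These bounds take the reads of the other libraries as exact, so the intervals can reach nearer to 0; on the log2 scale those of UGT75B1, AT4G27480, AT1G06000 and AT1G24881 start at 3.54, 3.67, 3.48 and 3.18. AT2G28440, AKR4C10 and AT1G80325 rest on libraries with 0 and 1 reads, and their log2 intervals start at 3.45, 3.34 and 3.10. On the deposited TPM values AKR4C10 was at 0.086 and AT1G80325 at 0.025. After subtracting the shift of all loci on that scale they were at -0.0013 and -0.063.

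Among the lowest loci, AT2G16586 was 24.5-fold lower, a log2 of -4.62 (-4.66 to -4.57), from 10133, 14575, 27015 and 132035 reads in the same order. AT5G61310 was 19.95-fold lower at -4.32 (-4.52 to -4.11). AT3G41762, AT2G01008 and MIR5642a lie within 10 kb of ribosomal RNA genes in the reference and stood at -5.29 (-5.61 to -4.98), -4.71 (-4.87 to -4.55) and -4.92. AT2G07599 at -5.0 (-5.77 to -4.22) lies in the copy of mitochondrial DNA on chromosome 2, so its reads may belong to mitochondrial transcripts. AT5G06043 was at -6.14 (-7.80 to -4.49) with 3 reads in the MTA-GFP IP. The snoRNA gene AT4G39363 was at least 1044-fold lower (log2 interval from -8.45 downward) and U1.10 at least 96.3-fold (from -5.21), and U6.3 stood at -8.09 (-10.41 to -5.76) with 1 read in the control input. The U1 and U6 genes have near-identical copies and their values are uncertain.

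Of the 34 nuclear-encoded photosynthesis genes, 33 were lower in the double ratio, with a median log2 of -1.68 relative to the typical locus, at percentile 0 among matched random lists, 1.63 on the share of reads and 0.13 on the deposited TPM values. LHCB1.3 and LHCB1.5, which encode light-harvesting proteins of photosystem II, were at -1.88 (-1.94 to -1.83) and -1.87 (-1.95 to -1.80). PSAL and PSAG of photosystem I were at -2.48 (-2.66 to -2.30) and -2.37 (-2.58 to -2.16). The 2 IPs compared directly gave a median of -0.14 for these genes, with 0 of 34 past the size rule, and the 2 inputs gave 1.59. Reads of the LHCB and RBCS families can be shared between paralogs. Of 5 phloem markers, 4 were lower, with a median of -2.09 relative to the typical locus and 1.22 on the share of reads. They were SUC2, the companion-cell sucrose transporter, at -2.84 (-3.21 to -2.46), APL at -2.32 (-3.90 to -0.74), the proton pump AHA3 at -2.09 (-2.43 to -1.74) and SULTR2;1 at -1.19 (-1.80 to -0.59). Between the IPs the phloem median was -1.53, with 3 of 5 lower.

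Of 109 snoRNA genes, 73 were lower and 1 higher, with a median of -2.90 relative to the typical locus and 0.37 on the share of reads. AT2G08770 was at -3.27 (-3.32 to -3.22) and AT5G02565 at -2.51 (-2.63 to -2.39). Of 21 snRNA genes, 12 were lower and 1 higher, with a median of -1.23 that turns to 0.48 on the deposited TPM values. Of 44 cytosolic ribosomal protein genes, 4 were higher and 5 lower, with a median of -0.41 that turns to 0.20 between the IPs alone and to 0.12 on TPM. The list also holds the plastid proteins RPL12-A at -1.69 (-2.40 to -0.98) and RPS9 at -1.50 (-2.02 to -0.97). Of 261 other non-coding RNA genes, 33 were higher and 42 lower, with a median of 0.22.

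Of 50 measured miRNA target mRNAs, 3 were higher and 5 lower, with a median of -0.05. SPL13, a target of miR156, had 16, 105, 29 and 0 reads in the MTA-GFP input, MTA-GFP IP, control input and control IP. Its log2 ratio of MTA-GFP IP over input was 0.82 (0.06 to 1.69), below the size rule. Whether shared reads were assigned to another locus was not examined for it. NFYA8, a target of miR169, was at 2.91 (1.21 to 4.61) in the double ratio. The most abundant targets, APS1 and TOE1, were at -0.62 (-0.96 to -0.29) and -0.44 (-0.77 to -0.11). Of 19 genes of miRNA biogenesis, 3 were higher and 0 lower, with a median of 0.05. They were MOS2, an RNA-binding protein needed for miRNA maturation, at 2.14 (1.23 to 3.04), CBP20, a cap-binding subunit, at 1.17 (0.23 to 2.11) and HESO1, which uridylates small RNAs, at 1.09. In MTA-GFP IP over its own input MOS2 and CBP20 were lower, at -1.20 (-1.66 to -0.75) and -1.13 (-1.69 to -0.58), and in the control pair they were at -3.33 and -2.30. DCL1, the nuclease that cuts primary transcripts, was at -0.56 (-0.81 to -0.31). None of the 5 writer subunits passed the size rule, with a median of -0.21, VIR at -0.21 (-0.70 to 0.27) and MTB at 0.60 (-0.03 to 1.22). Of 14 m6A readers and erasers, the readers ECT11 at 1.63 and CPSF30 at 1.26 (0.36 to 2.16) were higher and ECT4 at -1.12 (-1.84 to -0.41) was lower, with a median of 0.30. The reader ECT2 and the demethylase ALKBH10B were at -0.21 (-0.47 to 0.04) and 0.79 (0.29 to 1.3).

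The 15 clock genes had a median of 0.06 with none past the size rule, and GRP7 and GRP8, RNA-binding proteins under clock control, were at 0.44 (0.37 to 0.50) and 0.73 (0.61 to 0.84). Of 16 genes of wounding, touch and jasmonate response, the touch-induced TCH2 at 1.67 (1.09 to 2.26) and ZAT12 at 1.22 were higher and LOX2, an enzyme of jasmonate synthesis, was lower at -1.52 (-1.69 to -1.35), with a median of 0.15. Of 12 salicylate defence genes, SARD1 at 1.16 (0.58 to 1.75) and PAD4 at 1.1 (0.43 to 1.77) were higher, with a median of 0.05. None of 18 SR splicing factor genes (median -0.21), 7 guard cell markers (0.43) or 3 heat shock genes (1.42) passed the size rule. The trichome marker GL2 was at -0.37 (-1.24 to 0.49), the flower marker SHP1 was lower at -1.22 (-1.51 to -0.93), and PMI15, annotated as a pseudogene, was higher at 1.52 (1.25 to 1.79). Each was the 1 member of its list measured. Setting counts of 0 to 3 reads moved the median double ratio of the snoRNA genes by 0.049, and those of the other lists by less.

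**Figure D3:**
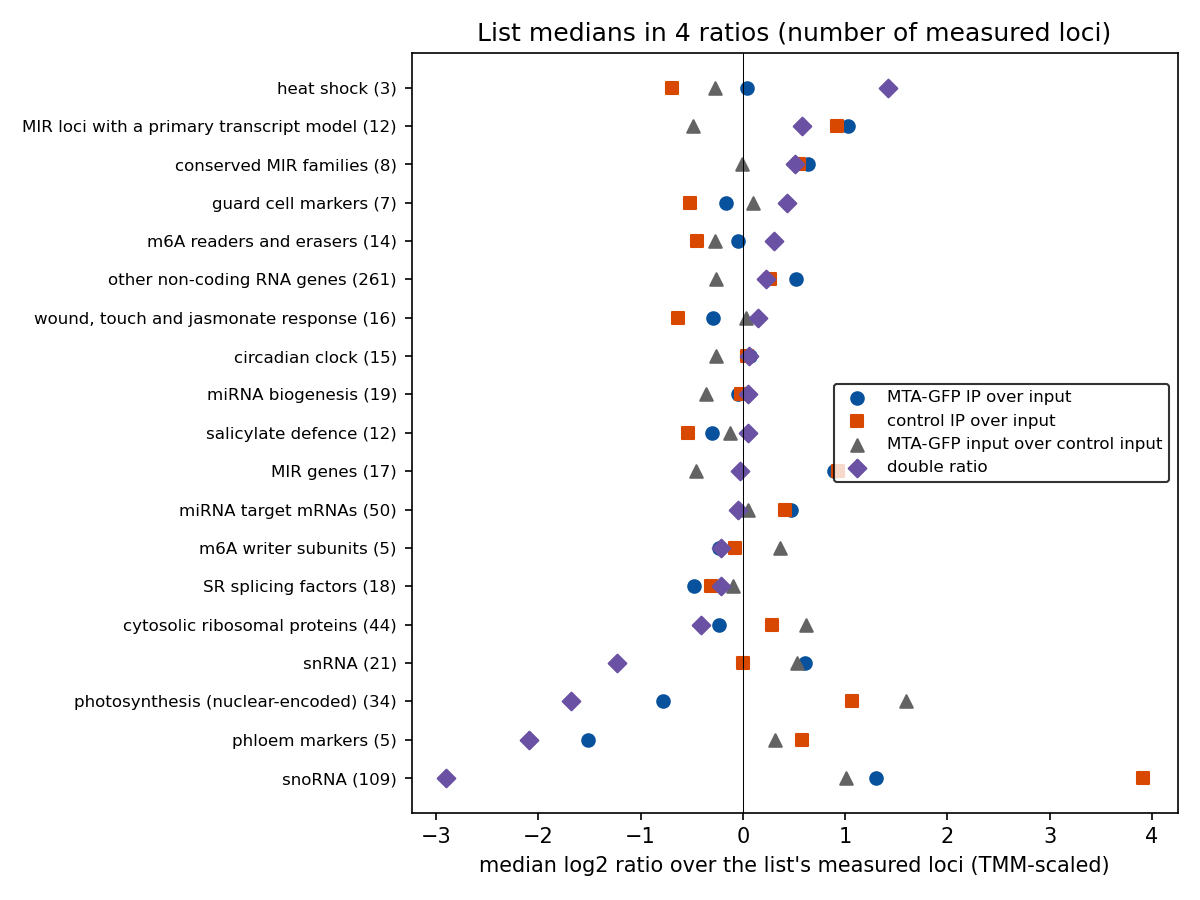
Median log2 ratio relative to the typical nuclear locus (x axis) of each gene list (y axis), in the 4 ratios. The snoRNA genes lie at 3.91 in control IP over input and 1.3 in MTA-GFP IP over input, and the photosynthesis genes at 1.59 between the inputs and -1.68 in the double ratio; on the share of all reads every double ratio is about 3.26 higher, so that these 2 lists stand at 0.37 and 1.63.

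MTA-GFP IP over input asks which nuclear RNAs came down with the tagged methylase. Small nuclear and nucleolar RNA genes and AT1G15405 led the loci that were higher relative to the typical locus, and a block of mitochondrial DNA inserted in chromosome 2 held the lowest. AT1G15405, a non-coding RNA gene, was 12.3-fold higher, a log2 of 3.62 (3.58 to 3.65). Of 15669 loci, 1124 were higher and 1328 lower, so 45.8% of calls were higher. This share was 99.5% when scaled to all reads, 99.4% to nuclear-encoded reads, 75.8% to mRNA reads and 87.5% on TPM. The self-test found 25 of 50 loci raised 2-fold and called 1.06% of unchanged loci.

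U1.2 was at least 56.0-fold higher, AT4G06305 at least 21.7-fold, and U6.4 was 21.3-fold higher (log2 4.41, 4.17 to 4.67), with the U1 and U6 copies uncertain. The snoRNA genes AT1G04277 at 3.85 (2.89 to 5.11), AT2G09690 at 3.81 (2.95 to 4.91), AT4G03925 at 3.70 (2.87 to 4.73) and AT1G06463 at 3.25 (2.84 to 3.71) were among the 10 highest. LpxC3, which has near-identical copies, was at 5.20 (3.47 to 8.39) with 2 input reads, and AT4G03905 at 5.23 (3.0 to 10.81) with 1. The 10 lowest were AT2G07708, AT2G07785, AT2G07727, AT2G07715, AT2G07641, AT2G07665, AT2G07696, AT2G07734, AT2G07751 and AT2G07599. AT2G07727 had the most reads and was 67.2-fold lower, at -6.07 (-6.30 to -5.86). The 59 loci of this block had a median of -5.04 with 56 lower, and -1.92 with 43 lower in control IP over input. Reads of the block may belong to mitochondrial transcripts, and the 2 were not told apart. The mitochondrial share of reads was also lower, at 0.149-fold in MTA-GFP IP over input and 0.474-fold in control IP over input.

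Among the lists, 56 of 109 snoRNA genes were higher and 19 lower, with a median of 1.3, while their summed reads were lower, at 0.824-fold (0.809 to 0.839) relative to the typical locus and 3.71-fold on the share of reads. Of 21 snRNA genes, 8 were higher and 10 lower, and their median of 0.61 turns to -0.19 at a minimum of 200 reads and to -1.19 with counts of 0 set to 3 reads. Of 50 miRNA targets, 6 were higher and 2 lower, with a median of 0.47 at percentile 100. Of the other non-coding RNA genes, 62 were higher and 21 lower, with a median of 0.52. On TPM these 2 medians were 0.099 and 0.073, or -0.0095 and -0.036 after subtracting the shift of all loci. Of the photosynthesis genes, 12 were lower, with a median of -0.78 relative to the typical locus and 1.39 on the share of reads, and the deposited TPM values turn it to 0.60. Of 5 phloem markers, 3 were lower, with a median of -1.52 relative to the typical locus and 0.58 on the share of reads, SUC2 at -2.26 (-2.54 to -1.99) and AHA3 at -1.84 (-2.10 to -1.59) among them. Of 12 salicylate genes (median -0.30), the markers PR2 and PR5 were lower, at -1.88 (-2.09 to -1.67) and -2.35 (-2.57 to -2.14).

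The remaining lists had medians between -0.48, for the SR genes with 2 of 18 lower, and 0.07, for the clock genes with 1 of 15 higher and 1 lower. Of 19 biogenesis genes, 1 was higher and 4 lower (median -0.04), and of 44 ribosomal protein genes 1 was higher and 6 lower (-0.23). Of 5 writer subunits, FIP37 was lower at -1.05 (-1.62 to -0.46; list median -0.23), and none of 14 readers and erasers passed the size rule (-0.05). Of 16 wound and touch genes, 3 were higher and 2 lower (-0.29). None of 7 guard cell markers (-0.17) and 3 heat shock genes (0.04) passed.

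Control IP over input shows what came down without tagged MTA. The snoRNA genes were the group furthest above the typical locus, and 91 of 109 were higher and 3 lower, with a median of 3.91 relative to the typical locus and 2.79 on the share of reads, and their summed reads were 5.99-fold and 2.72-fold on these scales. AT1G15405 was 184-fold higher, a log2 of 7.53 (7.42 to 7.64). Of 15669 loci, 1435 were higher and 1943 lower. Of all calls 42.5% were higher, against 2.34% when scaled to all reads, 23.5% to nuclear-encoded reads, 33.2% to mRNA reads and 81.3% on TPM, where 130 loci were higher and 30 lower. The self-test called 1.39% of unchanged loci.

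The snoRNA gene AT4G39363 was at least 282-fold higher and AT1G04223 at least 74.2-fold. AT1G06253 at 7.20 (6.55 to 8.07), AT1G06463 at 6.56 (6.16 to 7.04), AT2G09690 at 6.95 (6.03 to 8.40), AT2G09695 at 7.29 (6.14 to 9.39), AT4G03925 at 6.94 (5.88 to 8.75) and AT1G08937 at 7.36 (5.90 to 10.82), with 2 reads in the control input, were also among the 10 highest. U6.3 was at 10.45 (8.71 to 16.49) with 1 input read and is uncertain. At the other end, UGT75B1 was at least 41.5-fold lower and AT1G06000 at least 20.1-fold. AT1G56660 was 31.2-fold lower (log2 -4.96, -5.37 to -4.61), AT1G04800 29.4-fold (-4.88, -5.38 to -4.44), AT2G22795 20.8-fold (-4.38, -4.88 to -3.95) and U2.14 19.4-fold (-4.28, -4.38 to -4.18). AT2G07751 at -4.41, AT1G75190 at -4.26, AT3G23450 at -3.74 and AT3G10020 at -3.71 completed the 10 lowest. AT2G07751 lies in the copy of mitochondrial DNA, so its reads may belong to mitochondrial transcripts.

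Photosynthesis genes were higher here, 18 of 34 with 1 lower, at a median of 1.07 relative to the typical locus and -0.07 on the share of reads. LHCB1.5 was at 2.40 relative to the typical locus and PSAL at 1.59 (1.44 to 1.74). Of 50 miRNA targets, 11 were higher and 2 lower, with a median of 0.41 at percentile 99.9 relative to the typical locus and -0.73 on the share of reads. Of 44 ribosomal protein genes 5 were higher and 5 lower (median 0.29), and of 261 other non-coding RNA genes 73 were higher and 28 lower (0.27). The median of the non-coding genes was 0.0028 on TPM and 0 over loci with a read. After subtracting the shift of all loci these were -0.0090 and -0.013. Of 21 snRNA genes 9 were higher and 8 lower, and their median of 0 moves to 0.97 with counts of 0 set to 3 reads, since 4 members had a library with 0 reads. None of 5 phloem markers passed the size rule (0.58).

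Among the lists below the typical locus were the wound and touch genes (median -0.63, percentile 0.67, 3 higher and 3 lower of 16), the salicylate genes (-0.53, percentile 2.71, 4 lower of 12), the readers and erasers (-0.45, percentile 4.45, 4 lower of 14) and the SR genes (-0.32, 2 lower of 18). MOS2 was lower at -3.33 (-4.29 to -2.56), TCH2 at -2.03 and ALKBH10B at -1.29 (-1.71 to -0.90). Of 19 biogenesis genes 4 were lower (median -0.02), of 7 guard cell markers 1 (-0.52), of 3 heat shock genes 1 (-0.69) and of 15 clock genes 1 (0.04). None of the 5 writer subunits passed (-0.08).

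The 2 enrichments were related across loci. Pearson's r of their log2 ratios was 0.401 over 15669 loci (Spearman's rho 0.396) and 0.515 over the 1491 loci with at least 100 reads in each library, and loci are not independent replicates. Both IPs were higher than their inputs at 333 loci, where 102.9 would be shared by independent lists, and both were lower at 557, where 164.7 would be. At 31 loci MTA-GFP was higher and the control lower (139 for independent lists), and at 46 the reverse (122). The 2 ratios share no library.

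**Figure D4:**
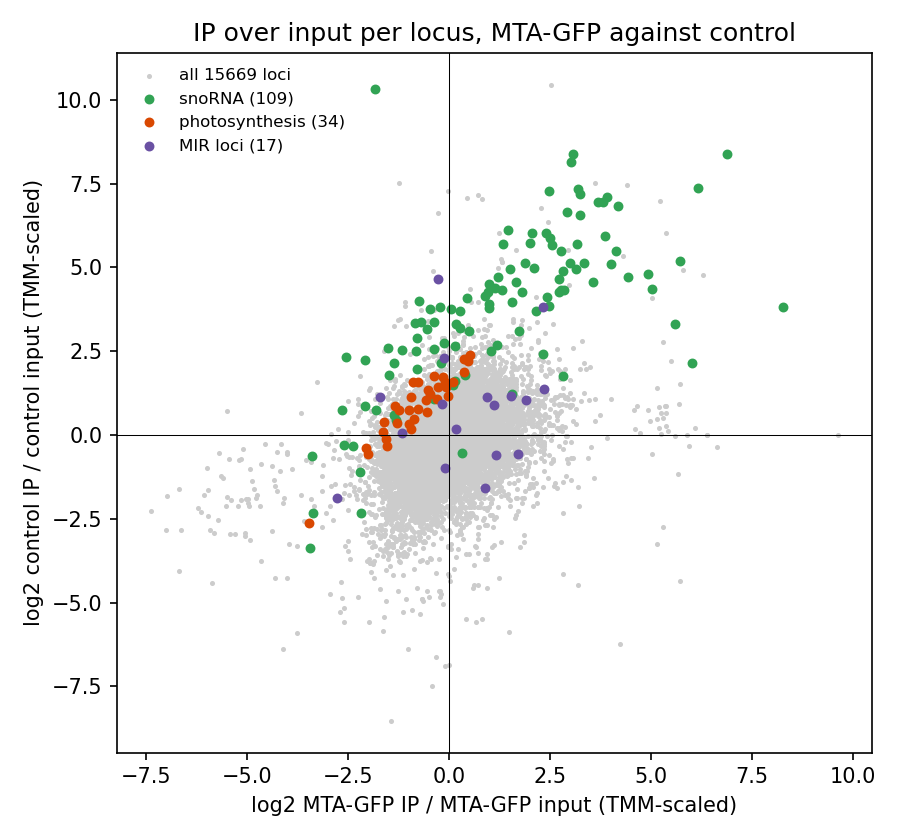
Log2 ratio of MTA-GFP IP over input (x axis) against control IP over input (y axis), both relative to the typical nuclear locus, 1 point per tested locus. The 2 ratios correlate with r of 0.401 over 15669 loci, and the snoRNA genes have medians of 1.3 on the x axis and 3.91 on the y axis.

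The inputs compare nuclear RNA of the MTA-GFP and control plants before precipitation. Besides MTA itself, photosynthesis genes were higher in the MTA-GFP input, 33 of 34, with a median log2 of 1.59 relative to the typical locus and 0.63 on the share of reads. LHCB1.3 was at 1.73, LHCB1.5 at 1.66, PSAL at 2.22 and PSAG at 2.06. Of 109 snoRNA genes 39 were higher and 2 lower, with a median of 1.01 relative to the typical locus and 0.07 on the share of reads. Of 15669 loci, 1100 were higher and 1063 lower. Of all calls 50.9% were higher, against 1.41% when scaled to all reads, 2.44% to nuclear-encoded reads, 44.6% to mRNA reads and 86.0% on TPM, where 43 loci were higher and 7 lower. The self-test called 1.27% of unchanged loci.

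The starch-related orphan gene QQS was 16.4-fold higher at 4.04 (2.89 to 5.88), AT1G15405 14.8-fold at 3.89 (3.78 to 4.00), and CLE16, which encodes a signalling peptide, at least 10.04-fold. AT2G05250 was at 5.68 (3.83 to 11.71), with 47 reads in the MTA-GFP input and 1 in the control input. AT2G05230, named below as lower, had 0 and 48 there. Division of shared reads between these loci could give both values, which are uncertain, and no sequences were compared. U1.10 was at least 80.9-fold higher, AT1G25055 at least 18.9-fold and LpxC1 at least 14.2-fold, while U6.3 and U6.4 were both at 7.22 (5.43 to 13.25), and these 5 have near-identical copies and are uncertain. Lower in the MTA-GFP input were AT1G56660, 5.05-fold (-2.34, -2.49 to -2.19), YAO, a nucleolar protein, 6.59-fold (-2.72, -3.30 to -2.21), and CML37, a calmodulin-like protein, 8.36-fold (-3.06, -3.99 to -2.32). U1.5 was at least 22.2-fold lower, AT1G17820 at least 14.3-fold, AT1G18010 at least 11.3-fold, AT2G08470 at least 9.22-fold, AT2G05230 at least 9.03-fold and AT4G06305 at least 8.66-fold. AT5G47360 was at -4.48 (-10.23 to -2.36) with 1 read.

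Of 44 ribosomal protein genes 6 were higher (median 0.61, percentile 100), and the jasmonate genes LOX2 at 1.99 and VSP2 at 1.19 were higher while TCH2 was lower at -1.35 (16 wound and touch genes, median 0.03). Of 19 biogenesis genes MOS2 at -1.13 and DDL at -1.25 were lower, with a list median of -0.36 at percentile 1.45. Of 15 clock genes GRP8 was lower at -1.19 (median -0.26), and of 14 readers and erasers CPSF30 at -1.14 (-0.27). Of 17 MIR loci 2 were higher and 1 lower (median -0.46), MIR775 at 2.28 (1.39 to 3.37) and MIR4228 at 1.14 upward and MIR5642a at -1.38 downward. Of 261 other non-coding RNA genes 22 were higher and 29 lower (-0.26), of 50 miRNA targets 2 and 3 (0.05), of 21 snRNA genes 6 and 1 (0.53, or 0.72 with counts of 0 set to 3 reads), and of 5 phloem markers 0 and 1 (0.31). Among writer subunits MTA was the 1 past the size rule (0.36). None of the 12 salicylate genes (-0.13), 18 SR genes (-0.09), 7 guard cell markers (0.10) or 3 heat shock genes (-0.28) passed.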

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

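The tests below were chosen after the results were seen, except that the comparison of the IPs without inputs and the scaling to all reads were fixed as alternatives before the data were examined. Each result below was picked out because it moved one way in the MTA-GFP pair and the other way in the control pair, because it was high in the control IP, or because it lies in entries that the comparisons of loci do not use. With 1 library per group the differences were not tested.

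The share of mRNA was higher in the MTA-GFP IP than in its input and lower in the control IP than in its input, a double ratio of 7.46. A lower share of organelle RNA in the MTA-GFP IP cannot be the whole account, because the double ratio among reads outside organelles was still 4.07. Reads of the tagged protein's own transcript cannot be either, because the MTA-GFP IP over input ratio without that locus was 3.66, as with it. A preparation that went differently in one of the lines cannot be told apart from the lines, with 1 library per group. Binding of mRNA by MTA-GFP may equally lie behind the difference and stays open, untested.

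The photosynthesis genes had a median log2 double ratio of -1.68 relative to the typical locus. The direct comparison of the IPs gave -0.14 over the 34 genes, so the low double ratio may come from the inputs, which differed by 1.59, rather than from the IPs. Harvest at different times of day cannot be told apart from the lines. CCA1 and LHY reads over TOC1 and LUX reads differed by a log2 of 0.25 (-0.38 to 0.88) between the inputs, from 36 and 190 reads in MTA-GFP and 68 and 427 in the control, whereas GRP8, PRR7 and GRP7, members of the clock list with more reads, were at -1.19, -0.85 and -0.72 in MTA-GFP input over control input, GRP8 past 2-fold, and PRR5, FKF1, ELF3, GI and ZTL were at -0.20, 0.22, 0.27, 0.46 and 0.54. More cytoplasmic RNA in the MTA-GFP input stays open, because the nuclear snoRNA genes were higher in that input by 1.01 while the other non-coding RNA genes were lower by 0.26 (a median of -0.26). A difference in expression between the lines also stays open, untested.

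The snoRNA genes lay above the typical locus by their median in both IPs, at 1.3 with MTA-GFP and 3.91 with the control. Relative to the typical locus their summed reads were 0.824-fold in MTA-GFP IP over input and 5.99-fold in control IP over input. On the share of reads the order was the reverse. There the sums were 3.71-fold with MTA-GFP and 2.72-fold with the control, and the medians 3.44 and 2.79. Binding to the beads without tagged MTA is consistent with the control IP, where their median was 2.79 even on the share of reads. The 32 other loci below 300 nt were raised less, with a median of 0.81 (quartiles -0.77 and 2.43) in control IP over input. The snoRNA genes had 3.91 (quartiles 2.43 and 5.15). The 2 groups were not matched on length within this limit or on expression, so an effect of short length cannot be excluded. Whether MTA binds any of the snoRNAs stays open, untested.

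The chloroplast share of reads had a double ratio of 0.133, lower with MTA-GFP and higher with the control. The share of unnamed structural RNA entries had a double ratio of 1.56, but without the 2 entries of 18S length it was higher in both IPs than in their inputs, 4.29-fold with MTA-GFP and 1.96-fold with the control. The pooled primary microRNA transcripts of loci with a model had a double ratio of 9.45 on the share of reads. The phloem markers had a median log2 double ratio of -2.09 relative to the typical locus. Outside the compared loci, the unnamed entries ENSRNA049494515 and ENSRNA049494585 held 13.3% of the reads of the MTA-GFP IP against 2.19% of its input, and 4.14% of the control IP against 1.09% of its input.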

How the results depend on the processing

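No paired analysis was possible because each group holds 1 library, and no library could be left out for the same reason. DESeq2 size factors changed none of the 8 counts of loci by over 1.5 times and moved none of 76 list medians beyond its spread. List medians and named loci were compared after subtracting the shift of all loci. Settings that change only the size factors (DESeq2 factors and total, nuclear or mRNA reads) therefore leave them nearly unchanged by construction. That stability is no test, and it enters the totals of list medians and named loci below. Over all alternatives 51 of 106 counts stayed within 1.5 times. Of 764 list medians 677 were counted as staying within their spread, 75 as moved and 12 as reversed. Of 1121 values of named loci 1050 kept direction and side of the size rule, 55 lost the rule and 7 gained it. Another 4 were counted as moved and 5 as reversed. Not every change of sign was counted as reversed. The MIR median double ratio went from -0.032 as reported to 0.035 on TPM, counted as within its spread. At a minimum of 1 read it was 0.81, counted as moved. List and gene values below are after subtracting the shift of all loci. The MIR median has no value at 200 reads, where fewer than 3 loci are left, and loci below a minimum have none. Lists of genes without an intron and of transposable element genes were not run, and single transcripts were run for the counts only. Where no reason is given, the cause was not tested. Values for mRNA totals, shares and left-out loci were chosen after seeing the data.

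Counts are given as higher and lower in the double ratio (1376 and 1399 as reported), MTA-GFP IP over input (1124 and 1328), control IP over input (1435 and 1943) and the inputs (1100 and 1063). Total reads of all genes gave 15124 and 24, 14580 and 77, 198 and 8255, and 97 and 6800. Total nuclear reads gave 13835 and 76, 14260 and 81, 851 and 2774, and 139 and 5559. These follow by construction from the shift of all loci. Total mRNA reads gave 2778 and 649, and 2101 and 670, in the first 2 ratios. A 3-fold rule gave 804 and 622, 505 and 373, 570 and 1013, and 342 and 360. A minimum of 200 reads, which leaves 7704 loci, gave 684 and 627, 356 and 587, 602 and 973, and 501 and 444. Single transcripts, 21779 in number, gave 5203 and 3216, 5230 and 3367, 3962 and 4972, and 3250 and 4167. A prior of 5 reads gave 849 higher in the double ratio and no interval gave 2374. The IPs without inputs gave 803 and 664.

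The deposited TPM values with a pseudocount of 0.5 gave 36 and 58, 140 and 20, 130 and 30, and 43 and 7, because 15387 of 15669 loci (98.2%) have a mean TPM below the pseudocount. On TPM the double ratio medians changed sign for photosynthesis (0.13), ribosomal proteins (0.12) and snRNA genes (0.48). So did that of photosynthesis in MTA-GFP IP over input (0.60), and the double ratios of MIR779 (-0.24), MIR4228 (0.14) and MIR167d (0.036). The TPM values that follow changed sign only through subtracting the shift of all loci. In MTA-GFP IP over input, miRNA targets went from 0.099 to -0.0095 and other non-coding RNA from 0.073 to -0.036. In control IP over input, other non-coding RNA went from 0.0028 to -0.0090. The double ratios of AKR4C10 and AT1G80325 went from 0.086 and 0.025 to -0.0013 and -0.063. At 200 reads the snRNA median of MTA-GFP IP over input was -0.19. At 1 read the MIR median double ratio was 0.81 over 103 loci. The control IP over input medians of other non-coding RNA, MIR loci and MIR loci with a model were all 0. Subtracting the shift made each -0.013. A value of exactly 0 is that of a locus without reads in either control library. Without inputs the ribosomal protein median was 0.20.

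The mRNA share ratios of 3.66 (MTA-GFP), 0.491 (control) and 7.46 (double) were 3.77, 0.678 and 5.55 per 18S read, 3.08, 0.756 and 4.07 outside organelles, and 3.68, 0.430 and 8.57 without AT2G16586. The pooled MIR models, at 1.39, 1.46 and 0.957 on TMM, were 6.25, 0.662 and 9.45 on the share of reads, with the control on the other side of 1. Per mRNA read the MTA-GFP and double values were 1.71 and 1.27, and without MIR775 1.78 and 1.26. Without MIR4228 and MIR5642a the MIR median double ratio was 0.18. The share of other non-coding RNA, 21.7 (MTA-GFP), 3.14 (control) and 6.90 (double), was 4.38, 0.660 and 6.64 without AT1G15405. That of all MIR loci, 14.6, 5.16 and 2.82, was 5.37, 0.699 and 7.68 without MIR4228 and MIR5642a. That of unnamed structural RNA, 1.32, 0.851 and 1.56, was 4.29, 1.96 and 2.19 without the 2 entries of 18S length, each of these 3 times with the control on the other side of 1. Of 325 MIR loci, 17 were measured.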

Other observations

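AT1G15405, a non-coding RNA gene, was among the loci furthest above the typical locus in 3 of the 4 ratios, and its log2 double ratio was -3.91 (-4.02 to -3.80), or 0.660-fold on the share of reads, so it rose more in the control pair. It held 5977 reads in the MTA-GFP input, 271014 in the MTA-GFP IP, 715 in the control input and 67598 in the control IP. The 2 IPs differed far less after scaling (114477 and 116314 scaled reads) than the inputs (9330 and 630), while as shares of reads the IPs differed 5.02-fold and the inputs 7.61-fold. CBF2 and CBF3, transcription factors of the cold response, and ZAT10, a stress-induced zinc finger protein, were higher in both IPs, at 1.14, 1.42 and 1.25 in MTA-GFP IP over input and at 1.33, 1.21 and 1.05 in control IP over input. SPL9, a target of miR156, the auxin receptor gene TIR1, NFYA3 and LCR were likewise higher in both, at 1.96, 1.16, 2.18 and 1.02 with MTA-GFP and 1.32, 1.24, 1.49 and 1.68 with the control. These genes were chosen after their values were seen.

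The files also list 27 models of transcripts that host microRNAs, 26 of them at loci with annotated transcripts, and 11 could be paired with the spliced transcripts of the same locus. The model's log2 ratio was above that of the spliced transcripts in 6 of 11 pairs for the double ratio, 7 for MTA-GFP IP over input and 5 for control IP over input. For MTA-GFP IP over input an exact two-sided sign test over these loci of the same libraries gave p = 0.549. Protein-coding loci of 1000 to 2000 nt had medians of -0.07 in MTA-GFP IP over input and -0.03 in control IP over input, and those of 4000 nt or more had 0.05 and 0.23. Non-coding loci below 300 nt, of which there were 149, had 1.05 and 3.30.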
